A study of Mus musculus with 16 samples.

How the data were processed

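Total RNA of whole hearts was extracted with Trizol from 16 mouse samples, 4 in each group of genotype and operation, per the labels. Per the same labels the RNA had an integrity number above 7, mRNA was selected with oligo(dT), the libraries carried a strand mark by dUTP, and paired ends were read on a NovaSeq instrument. Every sample was mapped to 1 column by its label, and 0 columns stayed unmapped. KO sham libraries 1 and 2 carry another label code than KO sham libraries 3 and 4, which the sources used here do not explain.

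The deposited table holds an estimated count per gene and library, made by the authors from aligned reads and not scaled for depth. The deposited FPKM values were made by the authors from the same reads and are scaled for transcript length and number of fragments, per the file headers. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, the GRCm38 genome, and DESeq2 and edgeR with no version. The role of each tool, the annotation release and the strand setting of the counting are not given in the sources used here. Among counts from 1 to 20, 31.5% were multiples of 4, against 25% for evenly spread numbers, and 14400 values were 4 against 6459 of 3 and 4633 of 5. A read pair thus appears to be worth about 4 counts, and the counts were also tested after division by 4. A count above 0 stood beside an FPKM of 0 in 67 values.

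The table holds 31258 genes, of which 31167 identifiers (99.7%) were found in the GRCm38 annotation at hand. 62 symbols were used by more than 1 identifier, and every test was run per identifier. Total counts per library ran from 64420776 to 73295756, with 26.1% to 28.7% in mitochondrial genes. Xist stood at 0 to 0.0304 FPKM and Ddx3y at 9.00 to 11.4 FPKM in all 16 libraries. Over the 24 pairs of libraries within a group, the chi-square per degree of freedom of the counts divided by 4 was 4.36 to 19.6. Read counting alone at 4 counts a read pair would give about 1. The lowest value was that of KO sham 1 and 2, and the highest that of KO sham 3 and 4.

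The tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Low counts were removed with filterByExpr (minimum count 10, minimum total count 15), which left 19219 genes. Libraries were scaled by TMM, and 1 model with a mean per group was fitted to all 16 libraries by edgeR's quasi-likelihood method. The tests were 4 pairwise comparisons (MI/R against sham in each genotype, KO against WT in each operation) and the interaction of genotype and MI/R. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison, with no minimum fold. The standard error of a log2 fold change came from the same model. The comparisons, the model, the gene lists, the rule for naming genes and the alternatives first planned were chosen before the data were examined.

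Gene lists were tested with camera with its preset correlation between members of 0.01, and again with an estimated correlation, each with Benjamini-Hochberg adjustment over the lists of a comparison. 38 lists were fixed, with 641 entries and 621 distinct genes, of which 595 were tested. 37 lists were tested, and the list of sex-linked genes served as a check of the libraries. A list's count of members is given over all genes tested and with the adjustment over the list alone. Atrial and skeletal muscle lists share members with the stress and contractile lists.

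Genes were named by a fixed rule. Prkn came first. In each comparison the rule took the 6 called genes with the largest change in each direction, of those with a mean of at least 5 FPKM in the higher group, a full separation of the libraries in the 4 pairwise comparisons, and a symbol other than a predicted-gene name. From each list it took the 2 called members of smallest adjusted p, or, where no member was called, the member of smallest p. The report names part of these genes. Gm20716, Dpm1, the brain genes and the glucocorticoid-responsive genes fall outside the rule.

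The alternatives were no filter, a filter of at least 5 FPKM in at least 4 libraries, DESeq2 on the counts, DESeq2 size factors in edgeR, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), limma on the TPM scale and after quantile normalization, robust variances, a block for the replicate number, the compared libraries alone, a fold change of at least 2, and leaving out each library in turn. Added after the data were seen were counts divided by 4, atrial and adipocyte list scores as covariates, KO MI/R against WT sham, fits without KO sham 1 and 2, KO sham 3 and 4, KO MI/R 3 and 4 or MI/R 3 and 4 of both genotypes, the set of 12 or 4 libraries as a term, and libraries 1 and 2 against 3 and 4 of every group as a term. List medians were also computed under 4 FPKM scalings: of 288 medians of 72 list shifts called, 10 had another sign than in edgeR. B cell markers, called in 2 comparisons, had too few members above the FPKM filter and stand outside this tally. No scaling moved the median of all genes by more than 0.1.

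The method was tested on simulated counts with 50 genes changed at each of 4 folds. Between KO MI/R and KO sham it called 12%, 38%, 56% and 78% of the genes changed 1.25-fold, 1.5-fold, 2-fold and 3-fold, with 8 false calls among 105. In the interaction it called 0%, 22%, 42% and 64%, with 4 false calls among 69. Between the MI/R groups there were 6 false calls among 98, and 0 calls in comparisons with no change put in. The totals of calls also hold members of the shifted list that follows. A list shifted on purpose had adjusted p = 2.51e-18 by camera, and 0 of 30 unshifted lists were called. The simulated genes were drawn independently of each other, so false calls of lists whose members vary together were not tested. Differences between sets or pairs of libraries were not simulated, and fewer genes were changed than were called in KO hearts. The shares called in the real comparisons may therefore differ.

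Reads of near-identical genes (H2-Q6 and H2-Q7, Hspa1a and Hspa1b, Hba-a1 and Hba-a2, and mitochondrial genes with nuclear copies) and of the overlapping genes Adnp, Dpm1 and Gm20716 may be assigned to the wrong gene, so their levels are uncertain. No raw reads were at hand, so alignment, transcript isoforms and the deleted part of Prkn were not examined.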

Results

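RNA was measured in 16 mouse heart samples by poly(A)-selected, paired-end sequencing. The hearts came from wild-type (WT) mice or from mice lacking Parkin in endothelial cells (KO), after a sham operation or after myocardial ischemia and reperfusion (MI/R, a stop of coronary blood flow followed by its return), with 4 libraries in each of the 4 groups. The series asks what the loss of Parkin in endothelial cells changes in the heart's response to MI/R. Each gene had an estimated count and an FPKM per library, and total counts ran from 64420776 to 73295756 per library. After removal of low counts 19219 genes were tested. Levels are given as mean FPKM ± SD (n = 4) and changes as log2 fold change ± SE, 4 libraries against 4. Adjusted p for genes came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and adjusted p for gene lists from camera over the 37 lists tested, all two-sided. No label says that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

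Prkn, the targeted gene, encodes the ubiquitin ligase Parkin (ENSMUSG00000023826, chromosome 17, 10840384 to 12063358, GRCm38). Its level was 0.524, 0.457, 0.447 and 0.547 FPKM in WT sham libraries 1 to 4, and 0.615, 0.661, 0.655 and 0.638 FPKM in WT MI/R libraries 1 to 4. In KO sham libraries 1 to 4 Prkn stood at 0.485, 0.558, 0.455 and 0.774 FPKM, and in KO MI/R libraries 1 to 4 at 0.479, 0.511, 0.794 and 0.405 FPKM. Prkn did not differ detectably between genotypes, with a log2 fold change of 0.13 ± 0.18 between sham groups (adjusted p = 0.843) and of -0.21 ± 0.18 between MI/R groups (adjusted p = 0.738), from counts of 284 to 596 per library. The injury changes of Prkn were 0.35 ± 0.18 in WT (adjusted p = 0.574) and 0.01 ± 0.18 in KO (adjusted p = 0.983), and their difference was -0.34 ± 0.26 (adjusted p = 0.631). The sources used here do not give the deleted part of the gene, and gene counts from whole hearts do not check a deletion in endothelial cells.

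**Figure D1:**
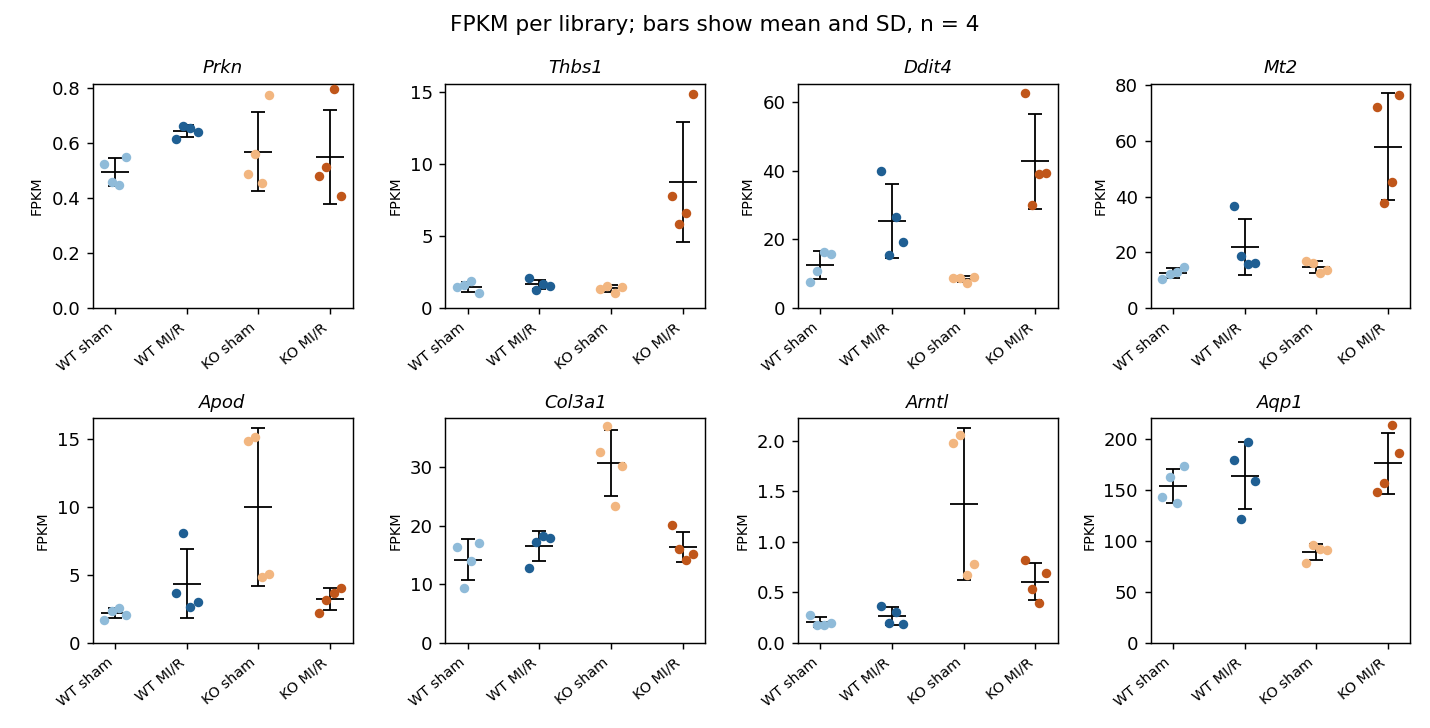
FPKM of 8 genes in each of the 16 libraries, by group; points are libraries, horizontal bars the mean and vertical bars the SD of 4 libraries. Thbs1 averaged 8.78 FPKM in KO MI/R against 1.63 FPKM in WT MI/R, and Prkn stood between 0.405 and 0.794 FPKM in all libraries.

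The first comparison asked which genes respond to MI/R in WT hearts. Ifi205 and Ifi207, of the interferon-inducible p200 family, rose. The change was 0.86 ± 0.12 for Ifi205 (adjusted p = 0.00793, from 3.56 ± 0.399 to 6.58 ± 0.56 FPKM) and 1.23 ± 0.22 for Ifi207 (adjusted p = 0.0456, from 2.49 ± 0.567 to 5.96 ± 1.64 FPKM). Fam107a, a stress-inducible regulator of actin, rose by 1.27 ± 0.20 (adjusted p = 0.0227). Arrdc2, an alpha-arrestin, rose by 1.19 ± 0.21 (adjusted p = 0.0388). Bcl2l1, which encodes the survival protein Bcl-xL, rose by 0.78 ± 0.13 (adjusted p = 0.0256, from 5.89 ± 0.688 to 10.3 ± 0.964 FPKM). Fam117b rose by 0.99 ± 0.16 (adjusted p = 0.0244). Scn4b, a beta subunit of the cardiac sodium channel, fell by 0.48 ± 0.087 (adjusted p = 0.0456). Ifi205 is ENSMUSG00000054203 (chromosome 1, 174011998 to 174031810), Bcl2l1 is ENSMUSG00000007659 (chromosome 2, 152780668 to 152831728) and Scn4b is ENSMUSG00000046480 (chromosome 9, 45138395 to 45154152).

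In WT hearts 18 genes were called between MI/R and sham, 15 higher and 3 lower, by edgeR's quasi-likelihood test, against 1881 at an unadjusted p below 0.05 and 169 called by DESeq2. Overlapping genes of 1 locus on chromosome 2 made up 3 of these 18 calls: Adnp and Dpm1, lower, and the predicted gene Gm20716, higher (Gm20716 and Dpm1 were chosen after their values were seen). Gm20716 (ENSMUSG00000093752, 168180986 to 168230364) spans both Dpm1 (ENSMUSG00000078919, 168209048 to 168230379) and Adnp (ENSMUSG00000051149, 168180986 to 168207112) on the same strand. Gm20716 had 39.9 to 58.7 CPM (counts scaled to the library total and its TMM factor) in the 4 WT MI/R libraries and 0 in the other 12, while Dpm1 and Adnp together had 17.4 to 39.1 against 72.3 to 85.8 CPM. The sum of the 3 genes was 69.8 to 80.0 CPM in WT MI/R and 72.3 to 85.8 in the other 12 libraries, so these 3 changes are uncertain as changes in single genes.

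No member of the 37 lists was called over all genes in WT hearts, and 16 lists shifted with the preset correlation. Interferon-stimulated genes, the antiviral response genes, had a median of 1.01, and 19 of 24 were higher adjusted over the list alone (adjusted p = 1.57e-10 preset, adjusted p = 0.321 with an estimated correlation). Their list score (mean log2 CPM of the members, each centred over all 16 libraries) was 1.56 in WT MI/R 2. It was -0.199, -0.345 and 0.093 in WT MI/R 1, 3 and 4 and -0.771 to -0.241 in WT sham, so most of the rise lay in WT MI/R 2. Cell cycle genes had a median of 0.47, and 7 of 20 were higher adjusted over the list alone (adjusted p = 2.72e-09 preset, adjusted p = 0.282 with an estimated correlation). Fibroblast markers had a median of 0.20 and 4 of 16 higher adjusted over the list alone (adjusted p = 1.16e-08 preset, adjusted p = 0.153 with an estimated correlation). Extracellular matrix genes had a median of 0.22 and 5 of 22 higher in that way (adjusted p = 1.36e-07 preset, adjusted p = 0.269 with an estimated correlation). Neutrophil markers had a median of 0.75 (adjusted p = 0.286 with an estimated correlation), monocyte and resident macrophage markers medians of 0.24 and 0.23 (adjusted p = 0.286 and 0.321 with an estimated correlation). Endothelial cell markers had a median of 0.17 with 0 of 16 called by either count (adjusted p = 0.000551 preset, adjusted p = 0.321 with an estimated correlation). Endothelial activation and adhesion genes had a median of 0.33, with 3 of 12 higher adjusted over the list alone (adjusted p = 0.00595 preset, adjusted p = 0.282 with an estimated correlation). Il1r1, the interleukin 1 receptor gene, was among them at 0.45 ± 0.13 (adjusted p = 0.235). Cell death mediators and immediate early genes had medians of 0.11 and 0.13 (adjusted p = 0.321 and 0.605 with an estimated correlation).

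Energy and contractile genes lay slightly lower after MI/R in WT hearts. Nuclear oxidative phosphorylation genes had a median of -0.11 (0 of 34 called, adjusted p = 2.23e-08 preset, adjusted p = 0.343 with an estimated correlation) and fatty acid oxidation genes a median of -0.13 (0 of 26 called, adjusted p = 5.88e-06 preset, adjusted p = 0.321 with an estimated correlation). Contractile markers and the cardiac stress programme had medians of -0.10 and -0.08 (adjusted p = 0.321 with an estimated correlation for both), and heat shock genes -0.09 (adjusted p = 0.618 with an estimated correlation). None of the 16 shifts was called with an estimated correlation. Of 25 alternatives, 17 ended the calls of Ifi207 and Scn4b each, 13 that of Arrdc2, 11 that of Fam117b and 10 that of Bcl2l1. The calls of Fam107a and Adnp were ended by 8 each, and that of Ifi205 by 2. Leaving out 1 library moved the 18 calls to 6 (without WT MI/R 4), 9 (without WT sham 1 or WT sham 2), or 11 (without WT MI/R 1 or WT MI/R 2). In sets of libraries described with the KO response, WT MI/R 1 and 2 gave 17 calls against WT sham, 16 higher and 1 lower, and WT MI/R 3 and 4 gave 37, 13 higher and 24 lower. A fit with the set as a term gave 4, with the calls of Fam107a, Ifi205, Ifi207, Arrdc2, Fam117b, Bcl2l1, Adnp and Scn4b lost. As the set holds MI/R libraries only, this fit takes the MI/R level from libraries 1 and 2.

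**Figure D2:**
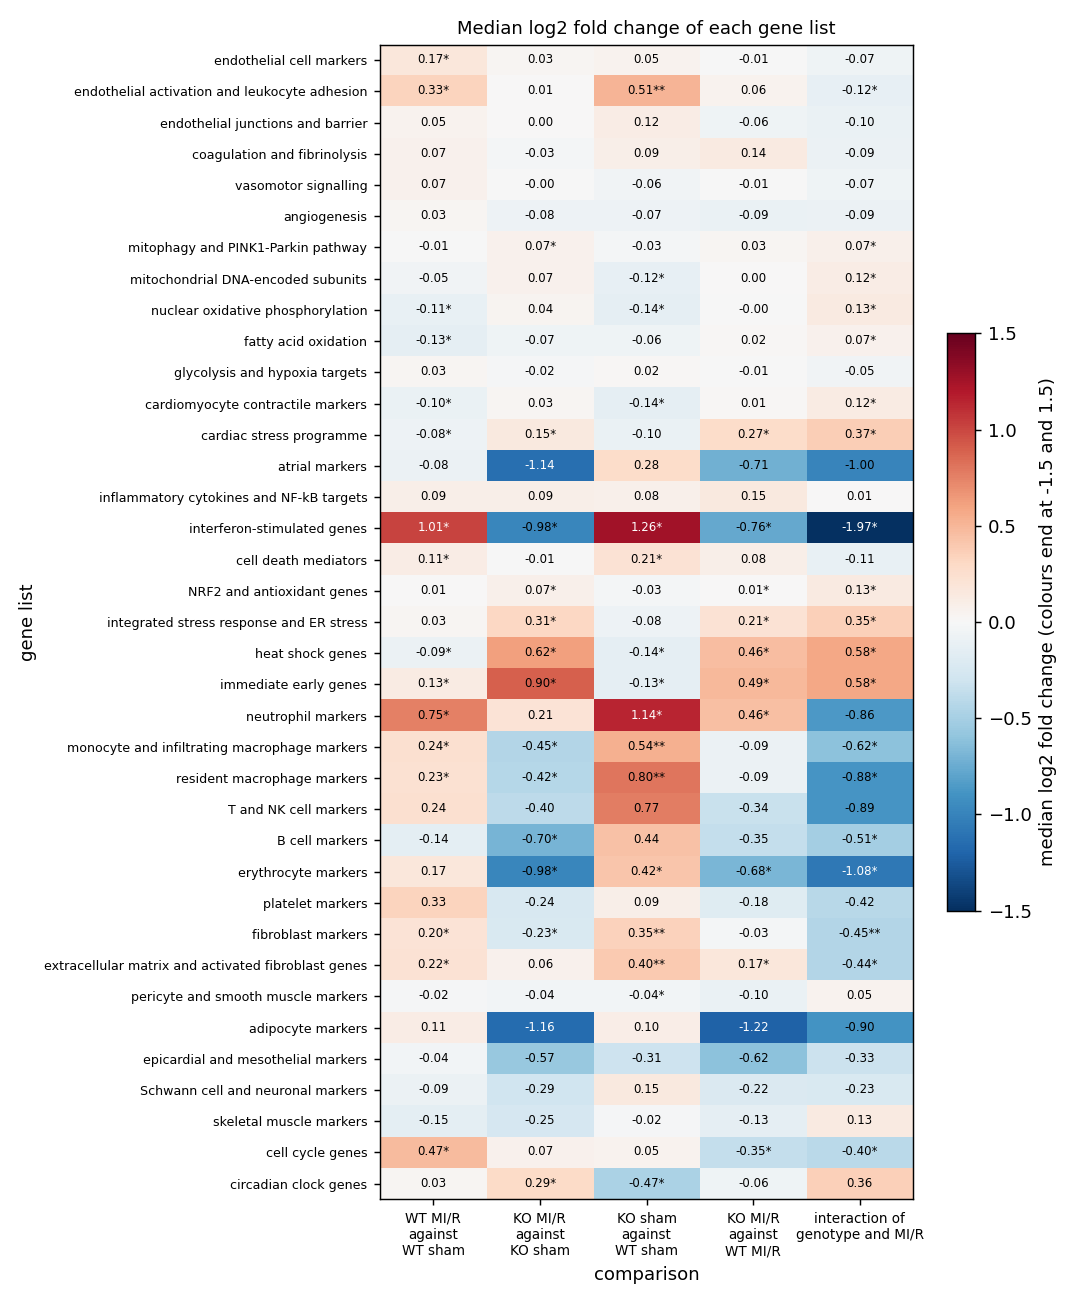
Median log2 fold change of each of the 37 gene lists (vertical) in the 5 comparisons (horizontal), printed in each cell and coloured from -1.5 to 1.5. An asterisk marks a list called by camera with the preset correlation and a pair of asterisks a list also called with an estimated correlation, which was the case for 5 lists in KO sham against WT sham and for 1 list in the interaction.

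The second comparison asked which genes respond to MI/R in KO hearts. Thbs1, which encodes the matrix glycoprotein thrombospondin 1, an inhibitor of angiogenesis, rose by 2.75 ± 0.26 (adjusted p = 2.4e-05, from 1.36 ± 0.214 to 8.78 ± 4.16 FPKM). Ddit4, a stress-induced inhibitor of mTORC1 signalling, rose by 2.39 ± 0.28 (adjusted p = 0.000105, from 8.5 ± 0.778 to 42.8 ± 14 FPKM). The metallothionein genes Mt2 and Mt1 rose, Mt2 by 2.02 ± 0.26 (adjusted p = 0.000211, from 14.8 ± 2.04 to 57.9 ± 19.3 FPKM) and Mt1 by 1.23 ± 0.17 (adjusted p = 0.000401). Fam107a rose by 2.24 ± 0.21, the kinase gene Map3k6 by 2.04 ± 0.17 and the steroid sulfate transporter gene Slc10a6 by 2.15 ± 0.24 (adjusted p = 2.4e-05, 2.4e-05 and 8.61e-05). Myoc, which encodes the secreted protein myocilin, fell by 1.23 ± 0.16 (adjusted p = 0.000211, from 6 ± 1.02 to 2.45 ± 0.39 FPKM). Alas2, the rate-limiting enzyme of heme synthesis in red cells, fell by 1.14 ± 0.20 (adjusted p = 0.0021). Thbs1 is ENSMUSG00000040152 (chromosome 2, 118111876 to 118127133), Ddit4 is ENSMUSG00000020108 (chromosome 10, 59949669 to 59951834), Mt2 is ENSMUSG00000031762 (chromosome 8, 94172664 to 94173568) and Myoc is ENSMUSG00000026697 (chromosome 1, 162639155 to 162649693). In KO hearts 1545 genes were called, 855 higher and 690 lower, by edgeR's quasi-likelihood test. The 9 genes just named kept their calls in each alternative run for this comparison.

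Apod (apolipoprotein D), Lgals3bp (a galectin-binding glycoprotein) and the class I histocompatibility genes H2-Q7 and H2-Q6 fell by 1.55 ± 0.39, 1.53 ± 0.42, 1.21 ± 0.33 and 1.19 ± 0.28 (adjusted p = 0.0203, 0.0341, 0.0299 and 0.0133). Each was higher in KO sham than in WT sham on average, at 10 ± 5.83 against 2.17 ± 0.382 FPKM for Apod, and the calls of Apod, Lgals3bp, H2-Q7 and H2-Q6 after MI/R were lost in 8, 12, 12 and 4 of 28 alternatives. Reads of H2-Q6 and H2-Q7 can be shared between these near-identical genes, so their levels are uncertain.

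Stress-response lists rose in KO hearts after MI/R. Of 20 immediate early genes 10 rose and 0 fell (14 higher adjusted over the list alone, median 0.90, adjusted p = 1.47e-11 preset, adjusted p = 0.152 with an estimated correlation). Among them were the transcription factor gene Maff at 1.73 ± 0.23 and the mRNA-decay gene Zfp36 at 0.92 ± 0.16 (adjusted p = 0.000242 and 0.00167). Among 15 heat shock genes 9 rose (10 adjusted over the list alone, median 0.62, adjusted p = 1.31e-09 preset, adjusted p = 0.239 with an estimated correlation). Their list score was 1.156 in KO MI/R 3, 0.051 to 0.245 in the other KO MI/R libraries and -0.323 to -0.068 in KO sham. The chaperone genes Hsph1 and Hspa8 rose by 1.09 ± 0.19 and 0.62 ± 0.096 (adjusted p = 0.00196 and 0.000859). Integrated and endoplasmic reticulum stress genes rose in 8 of 21 members (11 adjusted over the list alone, median 0.31, adjusted p = 5.19e-06 preset, adjusted p = 0.211 with an estimated correlation). Herpud1, which acts in the removal of misfolded proteins, and the transcription factor gene Xbp1 rose by 1.14 ± 0.12 and 0.40 ± 0.078 (adjusted p = 5.5e-05 and 0.00449). In the antioxidant list 5 of 21 rose and 1 fell (6 and 2 adjusted over the list alone, median 0.07, adjusted p = 0.301 with an estimated correlation). The cardiac stress programme had 5 of 17 members higher (7 adjusted over the list alone, median 0.15, adjusted p = 0.0111 preset, adjusted p = 0.434 with an estimated correlation). Gdf15, a stress-induced cytokine gene, and Ccn1, listed as Cyr61, rose by 1.64 ± 0.33 and 0.66 ± 0.13 (adjusted p = 0.00499 and 0.00519). Circadian clock genes rose in 4 of 15 members and fell in 1 (6 and 3 adjusted over the list alone, median 0.29, adjusted p = 0.503 with an estimated correlation). The clock repressor genes Per1 and Per2 rose by 1.15 ± 0.20 and 1.28 ± 0.23 (adjusted p = 0.00178 and 0.00282). Mitophagy genes rose in 3 of 23 members (6 adjusted over the list alone, median 0.07, adjusted p = 0.029 preset, adjusted p = 0.464 with an estimated correlation). The autophagy receptor gene Sqstm1 rose by 0.39 ± 0.074 and Gabarapl1 by 0.53 ± 0.094 (adjusted p = 0.0037 and 0.00221).

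Vascular genes moved both ways in KO hearts. Of 16 endothelial markers 5 rose and 2 fell (5 and 5 adjusted over the list alone, median 0.03, adjusted p = 0.584). The transcription factor gene Sox17 rose by 0.76 ± 0.11, and Kdr, the main VEGF receptor gene, fell by 0.78 ± 0.12 (adjusted p = 0.000643 and 0.00106). Barrier genes rose in 2 and fell in 2 of 16 members (the same numbers adjusted over the list alone, median 0.003, mean -0.15, an upward direction in camera, adjusted p = 0.895). The sphingosine 1-phosphate receptor gene S1pr1 and the junction gene Esam rose by 0.97 ± 0.12 and 0.54 ± 0.10 (adjusted p = 0.000221 and 0.00351). In the coagulation list 2 of 13 rose (3 higher and 1 lower adjusted over the list alone, median -0.03, mean 0.23, an upward direction in camera, adjusted p = 0.273). These were Serpine1, the inhibitor of fibrinolysis PAI-1, at 1.23 ± 0.18 and Thbd, the thrombin receptor thrombomodulin, at 0.40 ± 0.085 (adjusted p = 0.00051 and 0.00763). Ppargc1a, a regulator of mitochondrial gene expression, rose by 1.48 ± 0.24 (adjusted p = 0.00113) among 3 of 26 fatty acid oxidation genes, whose list did not shift (3 higher adjusted over the list alone, median -0.07, mean 0.006, a downward direction in camera, adjusted p = 0.683). Inflammatory genes rose in 2 of 21 members (2 adjusted over the list alone, median 0.09, adjusted p = 0.315). These were Nfkbia, the NF-kB inhibitor gene, at 1.14 ± 0.14 and Socs3 at 0.68 ± 0.17 (adjusted p = 0.000185 and 0.0216). The call of Socs3 was lost in 10 of 27 alternatives.

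Macrophage, B cell, fibroblast and red cell markers lay lower in KO hearts after MI/R than in KO sham, while neutrophil markers had a median of 0.21 with 1 of 14 higher and 0 adjusted over the list alone (adjusted p = 0.51). Resident macrophage markers fell in 5 of 16 members (1 higher and 9 lower adjusted over the list alone, median -0.43, adjusted p = 8.59e-05 preset, adjusted p = 0.464 with an estimated correlation). The complement receptor gene Vsig4 stood at -2.03 ± 0.41 and the fractalkine receptor gene Cx3cr1 at -1.79 ± 0.39 (adjusted p = 0.00532 and 0.00844). Monocyte and infiltrating macrophage markers fell in 2 of 19 (1 higher and 4 lower adjusted over the list alone, median -0.45, adjusted p = 0.503 with an estimated correlation). These were Csf1r at -0.49 ± 0.14 and Lyz2 at -0.39 ± 0.11 (adjusted p = 0.036 and 0.0369), calls lost in 15 and 12 of 28 alternatives. Fibroblast markers fell in 3 of 16 (1 higher and 8 lower adjusted over the list alone, median -0.23, adjusted p = 0.000532 preset, adjusted p = 0.301 with an estimated correlation). The collagen gene Col3a1 stood at -0.85 ± 0.17 and the proteoglycan gene Lum at -0.57 ± 0.075 (adjusted p = 0.00446 and 0.000276). Matrix genes split, with 3 of 22 higher, Thbs1 and the protease gene Adamts1 (0.54 ± 0.10, adjusted p = 0.00424) among them, and 4 lower (4 and 6 adjusted over the list alone, median 0.06, adjusted p = 0.731). Erythrocyte markers fell in 6 of 8 (8 adjusted over the list alone, median -0.98, adjusted p = 1.2e-08 preset, adjusted p = 0.152 with an estimated correlation), with Snca at -1.31 ± 0.27 (adjusted p = 0.0065). In the B cell list 1 of 13 fell (1 adjusted over the list alone, median -0.70, adjusted p = 0.301 with an estimated correlation). Interferon-stimulated genes had a median of -0.98 with 0 of 24 called and 10 lower adjusted over the list alone (adjusted p = 2.59e-06 preset, adjusted p = 0.593 with an estimated correlation), and without KO sham 1 and 2 its median was -0.004 with an upward direction in camera (adjusted p = 0.904). Without that pair the medians were -0.23 for monocyte and -0.23 for resident macrophage markers (adjusted p = 0.153 and 0.0268 preset, adjusted p = 0.88 with an estimated correlation for both), 0.02 for clock genes and 0.001 for mitophagy genes (adjusted p = 0.888 and 0.4). Mx1, an antiviral GTPase gene, stood at -1.72 ± 0.52 (adjusted p = 0.0513).

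DESeq2 called 2182 genes between KO MI/R and KO sham, and 4223 had an unadjusted p below 0.05. On log2(FPKM + 1) limma called 566 genes higher and 947 lower, and on the TPM scale 476 higher and 897 lower, against 855 and 690 with TMM scaling of counts. KO sham libraries 1 and 2 carried another label code than 3 and 4: the comparison called 875 genes without the first pair and 821 without the second. WT MI/R 3 and 4 and KO MI/R 3 and 4 had less RNA of brain genes than the other 12 libraries (12.6 to 16.2 against 20.2 to 25.8 CPM, scaled to the library total alone, summed over 15 genes). KO MI/R 1 and 2 against KO sham gave 435 calls and KO MI/R 3 and 4 gave 1407, with 422 calls when MI/R libraries 3 and 4 of both genotypes were left out, 506 without KO MI/R 3 and 4 alone and 775 with the set as a term. The fit with this term again takes the MI/R level from libraries 1 and 2. Leaving out 1 library moved the count over 1.5-fold in 2 cases, to 992 without KO MI/R 3 and 1016 without KO sham 4.

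The responses of both genotypes to MI/R were compared across the 19219 genes, which are not independent replicates and share no library. Their log2 fold changes had a Pearson r of 0.067 and a Spearman rho of 0.139. Of the genes called in both, 11 were higher in both (0.667 for independent lists), Fam107a and Bcl2l1 among them, and 1, Scn4b, was lower in both (0.108 for independent lists). Of the 1545 genes called in KO hearts 1089 had the same sign in WT hearts. The median absolute change of 5148 well-measured genes was 0.07 in WT and 0.10 in KO, and the median SD of log2 CPM within a group was 0.087 in WT sham, 0.091 in WT MI/R, 0.097 in KO sham and 0.11 in KO MI/R.

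**Figure D3:**
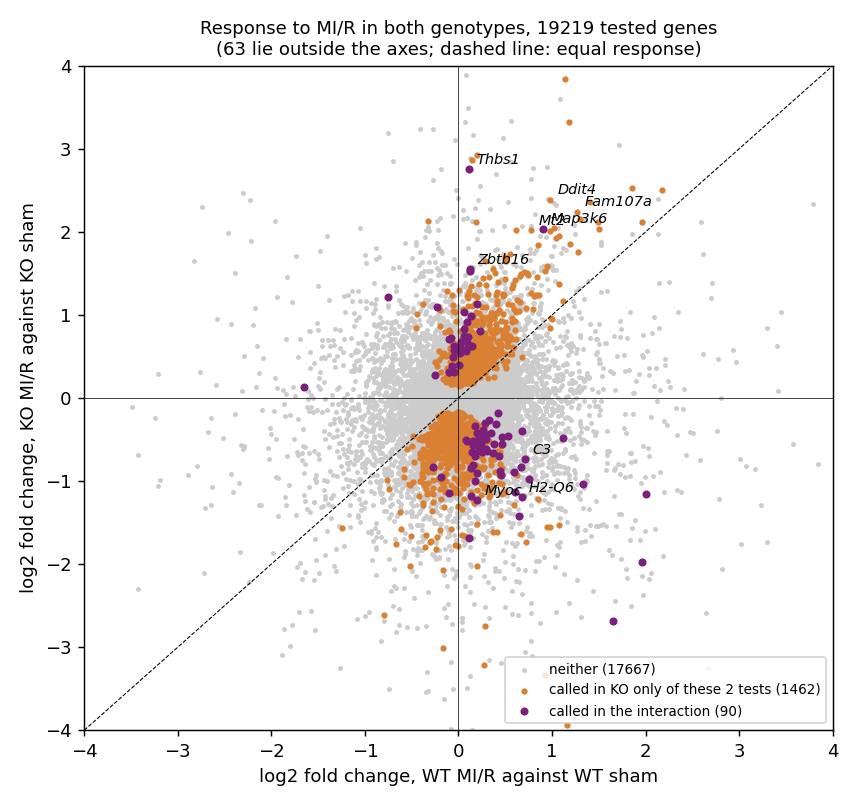
Log2 fold change after MI/R in WT (horizontal) and KO hearts (vertical) for 19219 genes; each point is a gene, orange if called in KO hearts and not in the interaction (1462), purple if called in the interaction (90) and grey otherwise (17667). 63 genes lie outside the axes, and Pearson r across genes was 0.067.

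The third comparison asked what the genotype changed without injury. Fibroblast and macrophage genes rose in KO sham hearts. Of 16 fibroblast markers 7 rose and 0 fell (12 higher adjusted over the list alone, median 0.35, adjusted p = 1.09e-19 preset, adjusted p = 0.0063 with an estimated correlation). Col3a1 rose by 1.04 ± 0.17 (adjusted p = 0.00655, from 14.2 ± 3.45 to 30.7 ± 5.64 FPKM) and Lum by 0.49 ± 0.075 (adjusted p = 0.00549). Resident macrophage markers rose in 7 of 16 members (13 adjusted over the list alone, median 0.80, adjusted p = 1.54e-19 preset, adjusted p = 0.0343 with an estimated correlation). The scavenger receptor gene Cd163 rose by 0.90 ± 0.17 and Adgre1, the F4/80 antigen gene, by 0.91 ± 0.18 (adjusted p = 0.0155 and 0.0216). Matrix genes rose in 4 of 22 (11 higher and 1 lower adjusted over the list alone, median 0.40, adjusted p = 3.19e-12 preset, adjusted p = 0.0323 with an estimated correlation). The protease gene Mmp14 rose by 1.18 ± 0.13 and the collagen gene Col5a2 by 0.69 ± 0.098 (adjusted p = 0.000388 and 0.00404). Col3a1 is ENSMUSG00000026043 (chromosome 1, 45311538 to 45349706), Lum is ENSMUSG00000036446 (chromosome 10, 97565128 to 97572703) and Mmp14 is ENSMUSG00000000957 (chromosome 14, 54431612 to 54441265).

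Monocyte markers rose in 1 of 19 members (12 adjusted over the list alone, median 0.54, adjusted p = 3.11e-11 preset, adjusted p = 0.0323 with an estimated correlation). It was the lysozyme gene Lyz2 at 0.63 ± 0.11 (adjusted p = 0.0107). In the endothelial activation and adhesion list 1 of 12 rose (5 adjusted over the list alone, median 0.51, adjusted p = 1.07e-05 preset, adjusted p = 0.0323 with an estimated correlation). The member called was Itgb2, a leukocyte integrin gene, at 0.95 ± 0.14 (adjusted p = 0.00404). With KO sham 3 and 4 only, the resident macrophage, matrix, monocyte and endothelial activation lists lost the call of the estimated correlation and kept that of the preset (adjusted p = 0.143, 0.133, 0.132 and 0.128 with an estimated correlation), while fibroblast markers kept both (adjusted p = 0.0203 with an estimated correlation). Endothelial markers did not shift (1 of 16 rose, 1 adjusted over the list alone, median 0.05, adjusted p = 0.106), the single call being Eng, the coreceptor endoglin, at 0.43 ± 0.093 (adjusted p = 0.0362). Pericyte and smooth muscle markers had a median of -0.04 (0 of 15 called, adjusted p = 0.0393 preset, adjusted p = 0.281 with an estimated correlation), which turned to 0.018 on log2(FPKM + 1) and 0.048 on the TPM scale.

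Genes outside these lists that rose in KO sham included Serpina3n, an acute-phase protease inhibitor (1.62 ± 0.36, adjusted p = 0.0413), C4b, a complement component (1.502 ± 0.321, adjusted p = 0.0336), H2-Q7 and H2-Q6 (1.61 ± 0.33 and 1.39 ± 0.28, adjusted p = 0.0287 and 0.0228) and the lysosomal protease gene Ctss (1.21 ± 0.22, adjusted p = 0.014). Apod rose by 2.12 ± 0.40 (adjusted p = 0.0153). Interferon-stimulated genes had a median of 1.26, with 0 of 24 called and 22 higher adjusted over the list alone (adjusted p = 4.06e-14 preset, adjusted p = 0.281 with an estimated correlation). Neutrophil markers had a median of 1.14, with 0 of 14 called and 6 higher adjusted over the list alone (adjusted p = 5.96e-07 preset, adjusted p = 0.0603 with an estimated correlation). The interferon median was 1.82 with KO sham 1 and 2 only and 0.06 with KO sham 3 and 4 only. Cell death mediators had a median of 0.21 and erythrocyte markers 0.42 (adjusted p = 0.224 and 0.358 with an estimated correlation). Sod3 (extracellular superoxide dismutase) rose by 0.52 ± 0.087 and Adm (adrenomedullin) by 0.81 ± 0.15 (adjusted p = 0.00823 and 0.0154).

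Clock genes changed in both directions in KO sham: 3 of 15 rose and 5 fell (3 and 9 adjusted over the list alone, median -0.47, adjusted p = 0.000276 preset, adjusted p = 0.266 with an estimated correlation), and a median of -0.15 with KO sham 3 and 4 only (adjusted p = 0.337). The core activators Arntl and Clock rose by 2.65 ± 0.36 and 0.57 ± 0.085 (adjusted p = 0.00342 and 0.00407), Arntl from 0.206 ± 0.0468 to 1.37 ± 0.749 FPKM. Per2, Tef and Hlf, which act in the opposite phase of the cycle, fell by 1.02 ± 0.23, 0.74 ± 0.13 and 0.96 ± 0.18 (adjusted p = 0.0445, 0.00977 and 0.0155), and Wee1, a clock-controlled kinase gene, by 0.79 ± 0.15 (adjusted p = 0.0152). Arntl stood 3.20 ± 0.28 above WT sham in KO sham 1 and 2 only and 1.75 ± 0.30 in KO sham 3 and 4 only (adjusted p = 0.000148 and 0.0631). Zbtb16, a zinc finger transcription factor gene, fell by 1.08 ± 0.16 and the water channel gene Aqp1 by 0.85 ± 0.14 (adjusted p = 0.00404 and 0.00741, Aqp1 from 154 ± 16.7 to 89.2 ± 7.61 FPKM). Myl2, the ventricular myosin light chain, fell by 0.45 ± 0.094 (adjusted p = 0.0287) as 1 of 17 contractile markers (4 adjusted over the list alone, median -0.14, adjusted p = 0.281 with an estimated correlation). Oxidative phosphorylation genes lay slightly lower, nuclear ones at a median of -0.14 (4 of 34 lower adjusted over the list alone) and mitochondrial ones at -0.12 (0 of 13; adjusted p = 0.324 and 0.358 with an estimated correlation), as did heat shock and immediate early genes at -0.14 and -0.13 (adjusted p = 0.542 and 0.503 with an estimated correlation).

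Between the sham groups 203 genes were called, 143 higher and 60 lower, by edgeR's quasi-likelihood test (2638 at an unadjusted p below 0.05, 587 by DESeq2). Limma on log2(FPKM + 1) called 199 higher and 27 lower, and on the TPM scale 252 and 22. With KO sham 3 and 4 only 7 genes were called, and with KO sham 1 and 2 only 490. Leaving out 1 library gave 46 to 432 calls, below 203 by more than 1.5-fold without KO sham 1 (64), KO sham 2 (46) or WT sham 1 to 4 (119, 65, 132 and 68) and above it without KO sham 3 (432). The scores of atrial and adipocyte markers as covariates gave 106 calls. Of 27 alternatives, 12 ended the call of Per2, 11 those of Serpina3n and H2-Q7 each, 10 that of Eng and 1 that of Col3a1. The calls of C4b, H2-Q6 and Myl2 were ended by 9 each, and that of Apod by 8.

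The fourth comparison asked what the genotype changed after injury. Thbs1 was higher in KO MI/R than in WT MI/R by 2.44 ± 0.26 (adjusted p = 0.000184, 8.78 ± 4.16 against 1.63 ± 0.341 FPKM) and was called in 26 of 26 alternatives, though not within MI/R libraries 1 and 2 (adjusted p = 0.11). Cdkn1a, the cell cycle inhibitor p21, was higher by 1.62 ± 0.29, Mt2 by 1.42 ± 0.25, Hsph1 by 1.10 ± 0.19 and Maff by 1.10 ± 0.22 (adjusted p = 0.03, 0.03, 0.028 and 0.049). Lower in KO were the noncoding RNA AU020206 at -0.85 ± 0.16, Lrrc3b at -0.56 ± 0.10, the kinase gene Plk2 at -0.53 ± 0.11 and Slc26a10 at -0.53 ± 0.10 (adjusted p = 0.0352, 0.0363, 0.0458 and 0.0384). Adnp, of the chromosome 2 locus, was higher by 1.57 ± 0.25 (adjusted p = 0.0217). Cdkn1a is ENSMUSG00000023067 (chromosome 17, 29090976 to 29100727) and Hsph1 is ENSMUSG00000029657 (chromosome 5, 149614287 to 149636376).

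Heat shock genes rose in 1 of 15 members over all genes and in 14 adjusted over the list alone (median 0.46, adjusted p = 1.34e-15 preset, adjusted p = 0.121 with an estimated correlation). Their list score was 1.156 in KO MI/R 3, 0.051 to 0.245 in the other KO MI/R libraries and -0.337 to 0.026 in WT MI/R. The antioxidant list rose in 3 of 21 members, Mt2 and the thioredoxin reductase gene Txnrd1 (0.31 ± 0.055, adjusted p = 0.03) among them (5 adjusted over the list alone, median 0.01, mean 0.16, adjusted p = 0.00124 preset, adjusted p = 0.249 with an estimated correlation). Immediate early genes had a median of 0.49 with 1 of 20 higher (6 adjusted over the list alone, adjusted p = 4.25e-06 preset, adjusted p = 0.29 with an estimated correlation). The cardiac stress programme had a median of 0.27 with 0 of 17 called (2 adjusted over the list alone, adjusted p = 3.42e-05 preset, adjusted p = 0.209 with an estimated correlation). Integrated stress genes had a median of 0.21 with 0 of 21 called (3 adjusted over the list alone, adjusted p = 0.249 with an estimated correlation), and neutrophil markers 0.46 with 0 of 14 (adjusted p = 0.388 with an estimated correlation). Erythrocyte markers had a median of -0.68 with 0 of 8 called and 7 lower adjusted over the list alone (adjusted p = 5.92e-09 preset, adjusted p = 0.121 with an estimated correlation). Cell cycle genes had a median of -0.36 with 0 of 20 called and 1 lower adjusted over the list alone (adjusted p = 0.418 with an estimated correlation). Interferon-stimulated genes had a median of -0.76 with 0 of 24 called by either count (adjusted p = 2.77e-06 preset, adjusted p = 0.659 with an estimated correlation). Their list score was 1.56 in WT MI/R 2, -0.345 to 0.093 in the other WT MI/R libraries and -0.496 to -0.134 in KO MI/R. Matrix genes, Thbs1 included, had a median of 0.17 with 1 of 22 called (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.492 with an estimated correlation). Endothelial markers, barrier genes, coagulation genes, vasomotor genes and angiogenesis genes had medians of -0.01, -0.06, 0.14, -0.008 and -0.09 with 0 members called over all genes (adjusted p = 0.831, 0.922, 0.171, 0.741 and 0.147). Mitophagy genes had a median of 0.03 with 0 of 23 called by either count (adjusted p = 0.205).

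Between the MI/R groups 53 genes were called, 38 higher and 15 lower, by edgeR's quasi-likelihood test (2317 at an unadjusted p below 0.05, 522 by DESeq2), and 21 higher and 16 lower by limma on log2(FPKM + 1). Within MI/R libraries 1 and 2 of both genotypes 2 genes were called and within libraries 3 and 4 86, and Thbs1 stood at 2.02 ± 0.33 and 2.79 ± 0.34 (adjusted p = 0.11 and 0.00363); 35 genes were called with the set as a term and 6 without libraries 3 and 4. Leaving out 1 library gave 5 to 115 calls: 5 without WT MI/R 4, 6 without KO MI/R 3, 8 without WT MI/R 2, 11 without WT MI/R 3, 12 without KO MI/R 4, 113 without WT MI/R 1 and 115 without KO MI/R 2. A fit of these 8 libraries alone called 3, and atrial and adipocyte scores as covariates gave 10. Of 26 alternatives, 16 ended the calls of Maff and Plk2 each, 14 that of Txnrd1, 13 that of Lrrc3b and 11 that of Hsph1. The calls of Cdkn1a, Mt2, AU020206 and Slc26a10 were ended by 12 each, and that of Adnp by 8.

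The interaction asked whether the response to MI/R itself differed between genotypes, and compared the KO change with the WT change. Thbs1 rose more in KO by 2.64 ± 0.35 (adjusted p = 0.00733), with an injury change of 0.11 in WT that was not called. This call held in 35 alternatives, and was lost with MI/R libraries 1 and 2 alone (2.22 ± 0.40, adjusted p = 0.0662) but not with 3 and 4 alone (2.99 ± 0.40, adjusted p = 0.0147). Zbtb16 and Aqp1 differed by 1.42 ± 0.22 and 0.98 ± 0.20 (adjusted p = 0.0174 and 0.0436), Zbtb16 rising from 8.62 ± 1.61 to 24.2 ± 2.53 FPKM in KO and standing at 17.4 ± 4.23 and 19.4 ± 2.75 FPKM in WT. Chaperone genes Hsph1 and Hspa8 differed by 1.32 ± 0.27 and 0.67 ± 0.14 (adjusted p = 0.0444 for both), Map3k6 by 1.14 ± 0.24 and Rhobtb1 by 0.93 ± 0.18 (adjusted p = 0.0481 and 0.04). The complement genes C3 and C1ra differed the other way, C3 at -1.44 ± 0.26 and C1ra at -1.02 ± 0.18 (adjusted p = 0.0297 for both), with C3 at 84.7 ± 7.61 and 48.9 ± 10.6 FPKM in KO sham and KO MI/R. Lower differences were also called for Myoc (-1.44 ± 0.22, adjusted p = 0.0174), H2-Q6 (-1.87 ± 0.39, adjusted p = 0.0481), H2-M3 (-1.03 ± 0.20, adjusted p = 0.0392), the interferon-inducible Ifi27 (-1.38 ± 0.28, adjusted p = 0.0444), Ly6c2 (-1.59 ± 0.34, adjusted p = 0.0498) and Sod3 (-0.59 ± 0.12, adjusted p = 0.0454). Zbtb16 is ENSMUSG00000066687 (chromosome 9, 48654297 to 48836222), Aqp1 is ENSMUSG00000004655 (chromosome 6, 55336432 to 55348555) and C3 is ENSMUSG00000024164 (chromosome 17, 57203970 to 57228136).

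Fibroblast markers were lower in the interaction, with 2 of 16 called, 10 adjusted over the list alone and a median of -0.45 (adjusted p = 3.85e-13 preset, adjusted p = 0.0368 with an estimated correlation). Lum stood at -0.72 ± 0.11 and Pi16 at -0.60 ± 0.12 (adjusted p = 0.0163 and 0.0443). This was the 1 list of 19 shifted ones called with an estimated correlation, and without KO sham 1 and 2 that call was lost (median -0.46, adjusted p = 0.106 with an estimated correlation). Interferon-stimulated genes had a median of -1.97 with 0 of 24 called and 22 lower adjusted over the list alone (adjusted p = 6.24e-19 preset, adjusted p = 0.189 with an estimated correlation), and without KO sham 1 and 2 the median was -0.89 (adjusted p = 0.657 with an estimated correlation). WT MI/R 2 bears on this value too, with a list score of 1.56 against -0.345 to 0.093 in the other WT MI/R libraries. Resident macrophage and monocyte markers had medians of -0.88 and -0.62, with 0 of 16 and 1 of 19 called and 11 and 9 lower adjusted over the list alone (adjusted p = 0.156 and 0.126 with an estimated correlation). Between the MI/R groups the fibroblast, resident macrophage and monocyte medians were -0.026, -0.085 and -0.087, with 0 called (adjusted p = 0.399, 0.846 and 0.574 by camera, preset). Between the sham groups they were 0.35, 0.80 and 0.54. The interaction of these 3 lists thus lay mostly in the sham difference. Heat shock genes had a median of 0.58, with 2 of 15 higher and 12 adjusted over the list alone (adjusted p = 9.48e-14 preset, adjusted p = 0.126 with an estimated correlation). The list score in KO MI/R was 1.156 in library 3 and 0.051 to 0.245 in the others. Immediate early genes and integrated stress genes had medians of 0.58 and 0.36, with 0 called and 6 and 7 higher adjusted over the list alone (adjusted p = 0.189 with an estimated correlation for both). Nuclear and mitochondrial oxidative phosphorylation genes had medians of 0.13 and 0.12, with 0 of 34 and 0 of 13 called by either count (adjusted p = 0.54 with an estimated correlation for both). Mitophagy and fatty acid oxidation genes had medians of 0.07 each with 0 called, 1 each higher adjusted over the list alone (adjusted p = 0.369 and 0.583 with an estimated correlation), which turned to -0.015 for each on log2(FPKM + 1) and -0.036 for each on the TPM scale. The cardiac stress programme and antioxidant genes had medians of 0.37 and 0.13, with 4 and 3 members higher adjusted over the list alone (adjusted p = 0.126 and 0.331 with an estimated correlation). Endothelial activation, B cell, erythrocyte, matrix and cell cycle genes had medians of -0.13, -0.51, -1.08, -0.44 and -0.40 (adjusted p = 0.272, 0.226, 0.0913, 0.369 and 0.369 with an estimated correlation). Adjusted over the list alone, 2, 1, 7, 6 and 0 of their members were lower. Without KO sham 1 and 2 the median of matrix genes was -0.21 (adjusted p = 0.131). Values without that pair are given here for the fibroblast, interferon and matrix lists only, so the other lists may depend on it too. Contractile markers had a median of 0.12 (adjusted p = 0.342 with an estimated correlation), which turned to -0.035 after quantile normalization.

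In the interaction 90 genes were called, 35 higher and 55 lower, by edgeR's quasi-likelihood test (2587 at an unadjusted p below 0.05, 606 by DESeq2), and 19 higher and 111 lower by limma on log2(FPKM + 1). The interaction called 1 gene with MI/R libraries 1 and 2 and 34 with libraries 3 and 4, 63 with the set as a term, 8 without KO sham 1 and 2 and 275 without KO sham 3 and 4. Of 35 alternatives, 26 ended the call of Map3k6, 21 those of Hsph1, Hspa8 and H2-Q6 each, 20 that of Pi16 and 19 those of Rhobtb1 and Ifi27 each. The calls of Aqp1 and Sod3 were ended by 17 each, C1ra by 10, C3 by 9, Lum by 4, Zbtb16 by 3 and Myoc by 2. For Ly6c2 and H2-M3 these numbers were 19 and 14 of 34. Leaving out 1 library gave 3 (without WT MI/R 4) to 222 calls (without KO sham 3), with 6 without KO sham 2, 8 without WT sham 2, 13 without WT MI/R 2, 22 without WT sham 1 or WT sham 4, 25 without KO MI/R 4, 31 without KO sham 1, 34 without KO MI/R 3, 40 without WT sham 3, 41 without KO sham 4, 53 without KO MI/R 2, 168 without WT MI/R 3 and 193 without WT MI/R 1.

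The KO injury comparison and the KO sham comparison share the KO sham libraries. Of 143 genes higher in KO sham 65 were lower after MI/R in KO (5.13 for independent lists), Col3a1 and Lum among them, and of 60 lower genes 32 were higher (2.67 for independent lists), Per2 among them. The correlation across genes of these changes was -0.479, against -0.498 in simulated unchanged groups with the same controls, and the covariance -0.145 against -0.119. With the KO sham libraries split between the comparisons, the correlation was -0.163 to -0.0307 and the covariance -0.0775 to -0.0168 over 6 halvings.

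Among the 37 lists 13 were called in no comparison: endothelial junctions and barrier, coagulation, vasomotor signalling, angiogenesis, glycolysis and hypoxia, atrial, inflammatory, T and NK cell, platelet, adipocyte, epicardial, Schwann cell and skeletal muscle genes. Atrial and adipocyte markers had wide shifts with no call: after MI/R in KO hearts their medians were -1.14 and -1.16 (adjusted p = 0.51 and 0.763), the latter with an upward direction in camera, and between the MI/R groups -0.71 and -1.22 (adjusted p = 0.389 and 0.101). Between the MI/R groups the medians of glycolysis and hypoxia genes and inflammatory genes were -0.009 and 0.15 (adjusted p = 0.6 and 0.129), the former with a mean of 0.025 and an upward direction in camera. The medians of T and NK cell, platelet, epicardial, Schwann cell and skeletal muscle markers were -0.34, -0.18, -0.62, -0.22 and -0.13 there (adjusted p = 0.846, 0.482, 0.121, 0.48 and 0.846), the last with an upward direction in camera.

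**Figure D4:**
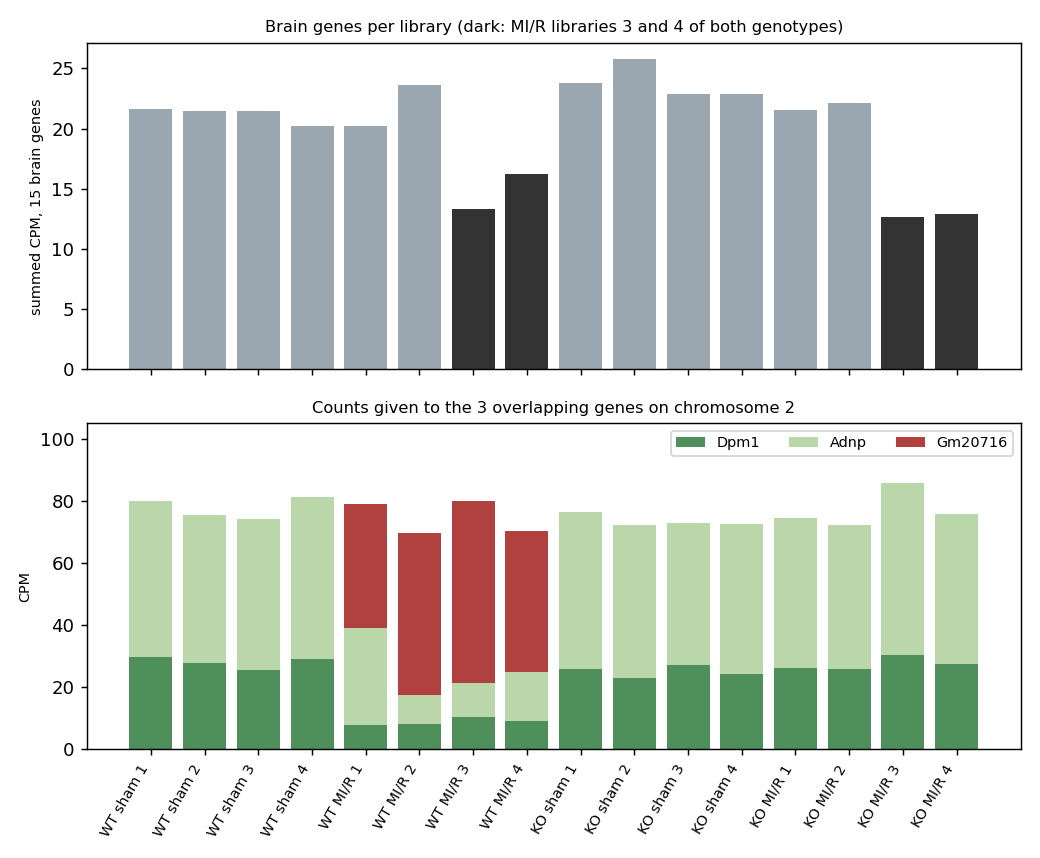
Above, CPM summed over 15 brain genes in each of the 16 libraries, with MI/R libraries 3 and 4 of both genotypes dark (12.6 to 16.2 against 20.2 to 25.8 in the other 12). Below, CPM of Dpm1, Adnp and Gm20716 stacked per library, with Gm20716 above 0 in the 4 WT MI/R libraries.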

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

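The tests of the KO sham baseline, of the set of MI/R libraries 3 and 4, of the cardiomyocyte share, with its scalings, and of KO sham 1 and 2 alone were chosen after the results they measure were seen. The tests with covariates, without both KO pairs and with other splits were set down before their own values were seen, some of them after related counts. KO sham 1 and 2 alone and KO MI/R 3 and 4 alone as explanations of the first pattern, and 3 explanations of the Gm20716 locus, were dropped after their values were seen.

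In 15 of 386 sets of 4 libraries, a library stood apart from the other 3 by Dixon's test at its 95% critical value, against 19.3 expected, since chance alone does so in about 1 of 20 groups. For list scores these were endothelial cell markers in WT MI/R 2 (-0.0871, others 0.0794 to 0.0858), cell death mediators in KO MI/R 2 (-0.109, others 0.102 to 0.127) and platelet markers in WT sham 2 (0.768, others -0.56 to -0.351). In WT sham, single libraries stood apart in FPKM for Arntl in library 1 (0.276, others 0.177 to 0.192) and Scn4b in library 4 (7.84, others 9.51 to 9.7). WT sham 3 stood apart for Serpina3n (9.46, others 5.88 to 6.35), Mmp14 (2, others 1.36 to 1.43), Sod3 (10.1, others 8.13 to 8.44) and Myoc (4.07, others 2.59 to 2.82). WT MI/R 1 stood apart for Fam107a (6.79, others 4.52 to 4.82), Cdkn1a (8.98, others 4.81 to 5.01) and Mt2 (36.7, others 15.7 to 18.8). In KO sham this held for Ddit4 in library 3 (7.34, others 8.8 to 8.99) and Socs3 in library 2 (2.65, others 1.83 to 1.91), and in KO MI/R for Snca in library 1 (0.599, others 0.434 to 0.459).

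A difference between the genotypes in the response to MI/R, tested as the interaction, was called by edgeR's quasi-likelihood test for 90 genes. Of 100 drawn splits of the libraries, 1 (the real one) called as many, and the highest other split called 28. The splits drew genotype anew within each operation, which removes every genotype difference, that of the sham hearts included. They argue against a random assignment of genotype, but do not test the interaction apart from a sham difference. With 1 library left out the count ran from 3 to 222. Among the genes named, the log2 differences were 2.64 for Thbs1, 1.42 for Zbtb16, 1.32 for Hsph1, 1.14 for Map3k6, 0.98 for Aqp1, 0.93 for Rhobtb1 and 0.67 for Hspa8. They were -1.87 for H2-Q6, -1.59 for Ly6c2, -1.44 for C3, -1.44 for Myoc, -1.38 for Ifi27, -1.03 for H2-M3, -1.02 for C1ra, -0.72 for Lum, -0.60 for Pi16 and -0.59 for Sod3.

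The same test called 19 lists with the preset correlation, and 1 of them, fibroblast markers, with an estimated correlation. The medians above 0 were 0.58 for heat shock genes, 0.58 for immediate early genes, 0.37 for the cardiac stress programme, 0.36 for integrated stress genes, 0.13 for nuclear oxidative phosphorylation, 0.13 for antioxidant genes, 0.12 for contractile markers, 0.12 for mitochondrial DNA-encoded subunits, 0.072 for mitophagy and 0.07 for fatty acid oxidation. Contractile markers turn to -0.035 after quantile normalization, and mitophagy and fatty acid oxidation to -0.036 on the TPM scale. Medians below 0 were -1.97 for interferon-stimulated genes, -1.08 for erythrocyte, -0.88 for resident macrophage, -0.62 for monocyte, -0.51 for B cell and -0.45 for fibroblast markers, -0.44 for matrix genes, -0.40 for cell cycle genes and -0.13 for endothelial activation. Those of fibroblast, resident macrophage and monocyte markers lay mostly in the sham difference, with medians of -0.026, -0.085 and -0.087 between the MI/R groups.

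The first pattern weighed was the number of genes called after MI/R, 1545 in KO against 18 in WT hearts. Random grouping of the libraries is argued against for each count: 1 of 35 splits, the real one, called as many. This is the smallest share that 35 splits can give, and the highest others called 1 in KO and 2 in WT. The WT count includes Adnp, Dpm1 and Gm20716 and fell to 4 with the set of libraries as a term. The set holds MI/R libraries only, so that fit takes the MI/R level from libraries 1 and 2. The fall may thus reflect fewer libraries behind the change. For the difference of 1527, 1 of 100 draws, the real one, was as large, and the highest other was 1157. These draws remove every genotype difference, that of the sham hearts included. KO MI/R against WT sham called 1033 genes, but this comparison joins a genotype difference to the injury. Genotype gave 203 calls between the sham groups and 53 between the MI/R groups. The 1033 calls therefore do not decide whether a shifted KO sham baseline is the whole cause. The 4 MI/R libraries with less brain RNA and both pairs of KO libraries are argued against as whole causes by 422 and 306 calls without them, when WT hearts gave 6 without the 4 libraries and 2 to 16 with 2 libraries a group, and 875 and 506 calls were left without KO sham 1 and 2 or KO MI/R 3 and 4. A stronger response in KO hearts or a shifted KO sham baseline may account for the rest, with differences in infarct size, harvest or litter between the groups left open. A gene called in KO and not in WT hearts is not thereby shown to respond differently. The interaction called 90 genes and KO against WT MI/R 53, and within MI/R libraries 1 and 2 they called 1 and 2. The median absolute log2 fold change of well-measured genes was 0.07 in WT and 0.10 in KO.

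A second pattern was the rise of fibroblast and resident macrophage markers in KO sham, with a median of 0.46 over 32 members (0.447 to 0.506 with each library left out). Random grouping of the libraries is argued against for the 203 calls of this comparison, as 1 of 35 splits, the real one, called as many. The highest other split called 2, and 1 of 35 is the smallest share these splits can give. Atrial and fat tissue in the samples is argued against by a median of 0.47 with both scores as covariates (0.432 to 0.551), and KO sham 1 and 2 alone by 0.435 with KO sham 3 and 4 only against 0.516 with 1 and 2 only. A lower cardiomyocyte share goes with contractile markers (median -0.14, and -0.075 to 0 under 4 FPKM scalings) and nuclear oxidative phosphorylation (-0.14), and as the whole cause it is argued against by pericyte and smooth muscle markers, whose upper quartile was 0.007 against a lower quartile of 0.331 for the lists that rose (0.029 to 0.096 against 0.286 to 0.378 under the same scalings). The contractile and nuclear oxidative phosphorylation medians were -0.065 and -0.091 with KO sham 3 and 4 only, and -0.176 and -0.187 with 1 and 2 only. More fibroblasts and macrophages, or more RNA of their marker genes in each cell, may account for the rise, and time of harvest and litter stay open, as clock genes differ too (Arntl by 2.65).

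The last pattern was in neuronal genes, which were lower in MI/R libraries 3 and 4 of both genotypes. Brain RNA added to MI/R libraries 1 and 2 is argued against by a first list of 12 brain genes: 0 of these 4 libraries lay above all other 12. From those values came the idea of low brain RNA in 12 libraries and less in 4, and a second list of 15 unseen genes gave 12.6 to 16.2 CPM in the 4 and 20.2 to 25.8 in the 12, with 16.2 the highest of the 4. Cardiac nerve and Schwann cells are argued against by a median difference of 0.035 for their list, against -0.56 for the first brain list. Mbp, 1 of the 10 tested members of the Schwann cell list, was itself lower in the 4 libraries, at -1.388 (adjusted p = 3.2e-05 by edgeR). A separate handling of the 4 libraries may account for the lower neuronal genes.

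Between the MI/R groups 53 genes were called, and 1 of 35 splits called as many, the real one. The highest other split called 52, and it was the split of MI/R libraries 1 and 2 against 3 and 4 of both genotypes. Within libraries 1 and 2, 2 genes were called between genotypes, and within libraries 3 and 4, 86. With the set as a term 35 genes were called.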

How the results depend on the processing

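The covariates, library pairs, sets and counts divided by 4 were chosen after results were seen. Over 109 gene results and 3053 alternatives, 2353 kept their side of the threshold and 700 lost their call. Of the results called in the main fit or the alternative, 0 changed sign. Prkn, which was not called, changed sign in some alternatives (-0.236 to 0.177 in KO hearts, -0.039 to 0.252 between sham groups). Thbs1 kept its call in these alternatives (log2 fold change 1.97 to 2.91 in KO hearts, 1.82 to 2.75 between MI/R groups, 1.89 to 2.80 in the interaction), and within MI/R libraries 1 and 2 lost it between MI/R groups (adjusted p = 0.11) and in the interaction (adjusted p = 0.0662). Of 3589 list alternatives 3281 kept their call or lack of it, 206 lost it, 85 gained it, 15 could not be tested and 2 turned: interferon-stimulated genes in KO hearts without KO sham 1 and 2 (upward, adjusted p = 0.904) and atrial markers between sham groups with covariates (downward, adjusted p = 0.0301). Where no construction is named below, the cause was not tested.

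Counts of calls moved over 1.5-fold from 18 (WT MI/R against sham), 1545 (KO MI/R against sham), 203 (KO against WT sham), 53 (KO against WT MI/R) and 90 (interaction) as follows. With no filter there were 6 in WT, 95 between sham groups, 8 between MI/R groups and 8 in the interaction, when more genes were tested. With a filter of at least 5 FPKM there were 45 in WT and 900 in KO, when fewer genes were tested. With only the compared libraries there were 10 in WT and 3 between MI/R groups. With a fold of at least 2 there were 7, 221, 40, 11 and 31, a stricter threshold. Limma gave 28 in WT and 33 between MI/R groups on log2(FPKM + 0.1), 23 between MI/R groups on the TPM scale and 53 in the interaction after quantile normalization. DESeq2 gave 169 in WT, 587 between sham groups, 522 between MI/R groups and 606 in the interaction, and 202 of the 203 and all 90 edgeR calls were among its calls in the sham groups and the interaction. With atrial and adipocyte covariates there were 106 between sham groups, 10 between MI/R groups and 147 in the interaction.

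Without KO sham 1 and 2 there were 875 in KO, 7 between sham groups and 8 in the interaction, and without KO sham 3 and 4 there were 821, 490 and 275. Without KO MI/R 3 and 4 there were 506 in KO, 5 between MI/R groups and 17 in the interaction. With the set of 12 or 4 libraries as a term there were 4 in WT, 775 in KO and 35 between MI/R groups, and without the 4 libraries 6 in WT, 422 in KO, 6 between MI/R groups and 8 in the interaction. The 4 libraries are all MI/R, so the term cannot be parted from injury in the comparisons with sham. Counts divided by 4, DESeq2 size factors, robust variances and libraries 1 and 2 against 3 and 4 of every group as a term moved no count over 1.5-fold.

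The replicate number as a block gave 11 calls in WT, 35 between MI/R groups and 57 in the interaction. No label says that a number marks a pair. Correlations between libraries of the same number were -0.104 to 0.113, and 10 of 16 libraries correlated best with their own number, a hint from the data that leaves some tie between them open.

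With an estimated correlation 0 lists were called in WT, 0 in KO, 5 between sham groups, 0 between MI/R groups and 1 in the interaction, against 16, 13, 16, 10 and 19 with the preset. Lists called in KO were 8 without KO sham 1 and 2, 8 without KO MI/R 3 and 4 and 8 without MI/R 3 and 4 of both genotypes. The correlation of the responses was 0.067, 0.197 by limma on log2(FPKM + 1), and 0.026 (without WT MI/R 1) to 0.149 (without WT MI/R 2) with a library left out. Leaving out each library gave 6 (without WT MI/R 4) to 22 calls in WT, 992 (without KO MI/R 3) to 1389 in KO, 46 (without KO sham 2) to 432 (without KO sham 3) between sham groups, 5 (without WT MI/R 4) to 115 (without KO MI/R 2) between MI/R groups and 3 (without WT MI/R 4) to 222 (without KO sham 3) in the interaction. The other libraries that moved a count over 1.5-fold stand in the report. At this depth and spread, the smallest simulated changes were called in 12% of genes in KO and 0% in the interaction.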

Other observations

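The glucocorticoid-responsive list was chosen after stress and clock genes were seen to rise in KO hearts, and before its own values were seen. The 12 or 4 libraries were defined from the data.

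A hypothesis is that genes responsive to glucocorticoids rose in KO hearts after MI/R. The list of 10 genes held out for it had p = 0.000657 by camera with an estimated correlation, with a median of 0.83 and 8 of 10 called. Errfi1 rose by 1.46 ± 0.19, Cebpb by 1.24 ± 0.15, Sgk1 by 0.89 ± 0.14, Glul by 0.77 ± 0.10 and Klf9 by 0.46 ± 0.074, while Angptl4 at -0.48 and Gadd45g at -0.03 were not called. With KO sham 3 and 4 only, the median was 0.77, with 6 called and p = 0.00317 by limma's camera with an estimated correlation. In WT hearts the median was 0.47 with 0 of 10 called. By limma's camera with an estimated correlation p was 0.00186 in WT and 0.101 in the interaction, so a difference between genotypes was not shown by that test, while KO against WT MI/R had 0.0296. The list may respond to other stress signals too, and no hormone was measured.

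Brain genes lower in the 4 MI/R libraries numbered 3 and 4 than in the other 12 included, chosen after their values were seen, Slc1a2 (2.03 to 3.17 against 5.72 to 7.57 CPM), Mobp (0 to 0.172 against 2.19 to 3.72) and Mbp (3.93 to 5.55 against 9.63 to 16.8). Mbp is also a member of the Schwann cell and neuronal list. Of the genes tested, 134 were lower and 38 higher in all 4 than in all 12 libraries, with 10.6 of each for a random choice of 4 libraries. The 4 are all MI/R libraries, the 12 hold every sham library, and the set was defined from the data. The excess over 10.6 therefore does not test the set. In the first list 5 of 12 and in the second 5 of 15 genes were lower in all 4. The first list had 55.0 to 62.3 CPM in the 4 libraries and 63.2 to 132 in the 12.

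The first 2 principal components of the 16 libraries held 12.4% and 8.83% of the variance. Among the genes called in KO hearts, those higher had median changes of 0.44 in KO and 0.13 in WT, and those lower had -0.55 in KO and -0.04 in WT.

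Some sham differences were larger in KO sham 1 and 2 than in 3 and 4. Apod stood 2.71 and 1.14 above WT sham in these pairs, Serpina3n 2.01 and 1.08, H2-Q7 2.07 and 0.93, while Lum stood 0.49 above it in both. The fibroblast list had adjusted p = 0.00559 with KO sham 1 and 2 only and adjusted p = 0.0203 with 3 and 4 only, with an estimated correlation, and the resident macrophage list 0.0486 and 0.143.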
